A study of Homo sapiens with 38 samples.

How the data were processed

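HaCaT cells, an immortalised human keratinocyte line, were exposed to medium treated with a non-thermal argon plasma jet, and their RNA was measured on NimbleGen one-colour arrays labelled with Cy3. Per the labels, the deposited values are normalized intensity values, and the submitters' processing notes name robust multichip averaging (RMA) without a version. The deposited intensities were linear. They were therefore taken to log2 with a pseudocount of 1, which the design fixed before the data were examined had allowed for linear values. Arrays give no read depth, and their number limits the precision.

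The deposited values covered 24000 transcripts, each under a RefSeq accession, with 0 missing values in 38 arrays. Symbols came from an annotation of GRCh38.p14 used for names only: 19125 transcripts matched 1 symbol and 4875 matched none, of which 2705 were predicted transcripts. They covered 17217 genes, of which 1464 had more than 1 transcript. The labels name no genome build, so no coordinates are given.

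The 38 arrays were 5 untreated arrays, 27 plasma arrays (3 for each of 20, 60 and 180 s of treatment at each of 3, 6 and 24 h), 3 arrays of medium treated with argon gas alone (1 for each gas duration) and 3 arrays of cells given 100 µM H2O2 (1 each at 3, 6 and 24 h). The labels give no time for the untreated and argon arrays, and nothing in them says that arrays of 1 group came from separate cultures. In 6 of the 9 plasma groups most transcripts of the median pair of arrays were nearly identical, and in the other 3 groups the share was 28.6% (20 s at 6 h), 19.2% (180 s at 24 h) and 4.15% (60 s at 24 h). The median SD of a transcript was below that of every set of 3 untreated arrays in all 9 groups, so each plasma group was averaged and counted as 1 sample, which left 20 samples. That step was chosen after the spread within groups was seen, and it lowers the number of samples that the design had assumed. Near identity meant transcripts within 0.01 log2 of the offset between a pair of arrays.

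Changes were tested with limma 3.58.1 (lmFit and eBayes, with the data.table package (1.17.8) and R 4.3.3) over all 24000 transcripts, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The untreated, argon and plasma samples were in 1 fit. A lone plasma sample was assumed to vary like the untreated and argon samples, since its own spread between cultures was not measured. The H2O2 arrays were fitted with the untreated and argon arrays, and 180 s of plasma was set against H2O2 with time as a factor. After the near identity was seen, comparisons that treat the 3 durations of plasma at 1 time as 3 samples were added, against untreated and against argon, together with comparisons of durations blocked by time and of times blocked by duration. The p-values measure only the spread between these samples, which may be technical. Counts at an unadjusted p under 0.05 are not counts of changed transcripts, since a share of about 0.05 of unchanged transcripts reaches that level. A lone untreated array set against the other 4 gave 196 to 2625 of them on the deposited scale. Each untreated array gave more of them after the quantile normalization described below.

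The argon and H2O2 arrays had another distribution of intensities than the others, from scaling, background or hybridization that the deposited values cannot separate, so every comparison was repeated after quantile normalization over all samples, and changes of named genes in comparisons that hold those arrays are quantile-normalized values. Other alternatives were median centring, removal of the 25% of transcripts with the lowest mean, eBayes with trend and robust settings, array weights, averaging of transcripts per gene, fits of the compared groups alone, argon as the control, the arrays as deposited, a block on the replicate number and leaving out each sample in turn.

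Gene lists (26) were written before the data were examined. They covered NRF2 targets and regulators, other antioxidant enzymes, heat shock proteins, ATF4 and the unfolded protein response, immediate early genes, p53 and NF-kB targets, growth factors, cell cycle, keratinocyte, metallothionein, cholesterol, glycolysis, interferon, proteasome, ribosome, mitochondrial chain and apoptosis genes, reference genes, and markers of 4 other cell types (fibroblasts, melanocytes, leukocytes and endothelium). They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. List medians were also ranked among 10000 random lists of the same size, matched on mean level in 40 bins. When each untreated array in turn stood in as a lone sample against the other 4, camera with the preset correlation called 7, 5, 5, 0 and 4 lists and camera with the estimated correlation 0 each time. Calls with the preset correlation alone are therefore weak evidence in comparisons with a lone sample.

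Genes were named by a rule fixed before the data were examined. For 180 s of plasma at each time it took the 10 largest rises and the 10 largest falls among transcripts with 1 symbol past the threshold, and for each other comparison 5 of each. It also allowed members of the gene lists, and it followed HMOX1, NQO1, GCLM, HSPA1A, DDIT3, FOS, HBEGF, IL6, CXCL8, VEGFA, CDKN1A and SOD2 in every comparison. A gene with several transcripts was taken at the one with the highest mean. Names outside the rule are marked as chosen after their values were seen.

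The pipeline was tested on simulated data with known changes. For 180 s of plasma at 3 h against untreated, 5.97% of genes changed 2-fold, 77.6% of those changed 4-fold and 95.5% of those changed 8-fold were called, each out of 66 or 67 genes. For 180 s against 20 s at 3 h the shares were 0, 19.4 and 81.8%, and for the 3 durations at 6 h against untreated 40.3, 95.5 and 100%. Comparisons that share the untreated arrays were set beside 100 simulations of unchanged groups against those arrays. Lists, splits of samples and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.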

Results

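The series measured RNA in HaCaT keratinocytes after exposure to cell culture medium that a non-thermal argon plasma jet had treated for 20, 60 or 180 s (100, 300 and 900 ms·µL per cell). Such medium carries reactive oxygen and nitrogen species, and per the labels cells were exposed for 2 h and then kept in fresh medium for 1, 4 or 22 h, up to harvest at 3, 6 or 24 h. The H2O2 cells had the same medium change, while the labels give neither a time nor a medium change for the untreated and argon cells, so comparisons with untreated cells are not known to be matched for it. There were 9 plasma groups of 3 arrays, 5 untreated arrays, 3 arrays with argon gas alone as the carrier control and 3 arrays with 100 µM H2O2 as the oxidant control. Lower quartiles of intensity ran from 268 to 270 in untreated arrays and from 267 to 319 in plasma arrays, but from 78 to 81 in argon arrays and from 99 to 107 in H2O2 arrays. Their distribution of intensities thus differed from that of the others.

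The 3 arrays of a plasma group differed from each other far less than the untreated arrays did. The median SD of a transcript was 0.28 log2 in the 5 untreated arrays and 0.33 in the 3 argon arrays. In plasma groups it was at most 0.10 log2, at 60 s and 24 h, and as low as 0.0079 at 180 s and 6 h, where 74.1% of transcripts of the median pair lay within 0.01 log2 of the pair's offset. Each of the 10 sets of 3 untreated arrays gave a median SD between 0.207 and 0.301. Each plasma group therefore entered the tests as 1 sample with no replicate check of its own.

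**Figure D1:**
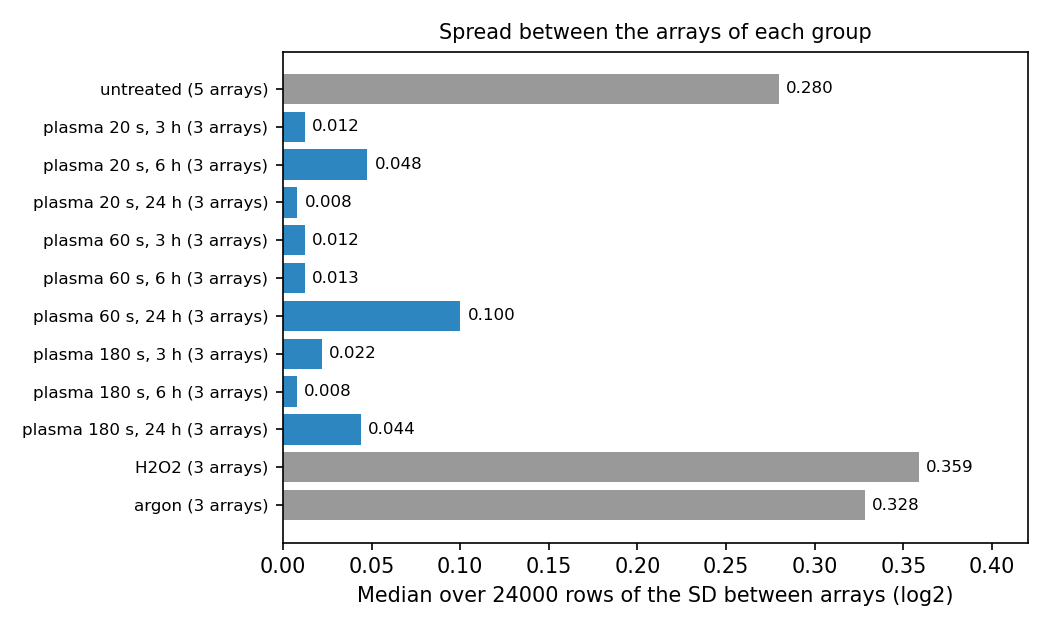
Spread within groups: the median SD of a transcript (log2) over the arrays of each group, drawn per group. The 9 plasma groups lie at or below 0.10 log2, while the untreated arrays lie at 0.28.

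The first question was what the longest plasma treatment did after 3 h. HMOX1 (NM_002133), which encodes the haem oxygenase that cells induce under oxidative stress, was 2.15 ± 0.46 log2 higher (SE, 1 sample against 5), or 4.43-fold, with a limma adjusted p of 0.227. FOS, an immediate early transcription factor gene, was 1.98 ± 0.46 higher, DUSP1, a phosphatase gene that damps MAP kinases, 2.00 ± 0.55 higher, and CHAC1, a glutathione-degrading target of the stress factor ATF4, 2.74 ± 0.71 higher (limma adjusted p = 0.236, 0.278 and 0.261). The epidermal growth factor receptor ligand genes EREG (1.38 ± 0.41) and HBEGF (0.97 ± 0.35) had positive values too, while the NRF2 targets NQO1 and GCLM stood at 0.57 and -0.01. limma called 0 of 24000 transcripts, against 3023 at an unadjusted p under 0.05. The immediate early list had a median of 0.86 log2 with 26 of 26 genes positive, and 12 genes rose when adjusted over the list alone. Its camera adjusted p was 2.6e-10, and adjusted p = 0.72 with an estimated correlation. The ATF4 and unfolded protein response list had a median of 0.46 with 19 of 23 positive and 5 genes higher when adjusted over the list alone (camera 2.1e-05, adjusted p = 0.62 with an estimated correlation). NF-kB targets (0.62, 18 of 24 positive, camera 0.019) and growth factors (0.30, 22 of 27 positive, camera 0.0045) passed with the preset correlation alone, with an adjusted p = 0.82 with an estimated correlation for both, and NRF2 targets did not pass (0.14, 19 of 32 positive, camera 0.57).

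At 6 h after 180 s, 8394 transcripts differed from untreated by limma, 4349 higher and 4045 lower. The labels give the untreated arrays no time, so treatment cannot be told apart from time or batch. Lower quartiles of intensity were 318 to 319 in the 180 s arrays, against 268 to 270 in untreated ones. Upper quartiles were 3920 to 3929, against 4401 to 4495. By untreated level in 5 classes, the median change from the lowest to the highest was 0.42, 0.86, -0.66, -0.26 and -0.04. HMOX1 rose by 2.24 ± 0.46 log2, or 4.71-fold (SE, 1 sample against 5, limma adjusted p = 0.00455). The NRF2 targets TXNRD1 (thioredoxin reductase, 1.32 ± 0.28), SLC7A11 (the cystine importer, 1.29 ± 0.35) and OSGIN1 (1.80 ± 0.52) rose with it, while the aldo-keto reductase genes AKR1B10 (-1.78 ± 0.32) and AKR1C3 (-0.95 ± 0.24) fell. HBEGF rose by 1.58 ± 0.35 and VEGFA, an angiogenic growth factor gene, by 1.29 ± 0.35 (limma adjusted p = 0.00632 and 0.0172), and EREG by 1.62 ± 0.41, while FGF2 fell by 1.52. Among immediate early genes and MAP kinase phosphatases, DUSP8 rose by 2.17 ± 0.27 (limma adjusted p = 0.00056), DUSP1 by 1.89 ± 0.55 and FOS by 1.39 ± 0.46. The ATF4 targets CHAC1 (2.81 ± 0.71), SESN2 (1.94 ± 0.36) and TRIB3 (1.30 ± 0.33) also rose, with limma adjusted p of 0.012, 0.003 and 0.012.

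In other gene lists at 180 s and 6 h, changes went both ways. The p53 targets RRM2B, a ribonucleotide reductase gene (-2.40 ± 0.25 log2), and TP53INP1, a gene of p53-driven cell death (-2.51), fell, while the cell cycle inhibitor gene CDKN1A stood at 0.60. The interferon-stimulated antiviral genes OAS2 (-2.22 ± 0.38) and IFIT1 (-1.65 ± 0.34) fell with limma adjusted p of 0.002 and 0.0044, while ISG20 and IRF7 rose by 1.51 and 1.43. NQO1 (0.53), GCLM (0.16), HSPA1A (-0.35), DDIT3 (0.72), IL6 (1.07), CXCL8 (0.85) and SOD2 (-0.05) did not pass. The 10 largest rises were in APOBEC1, OR14A16, SPI1, ASB10, OR52J3, SNX20, OPN1MW, HCRT, CALCA and ATP1B2, from 3.41 ± 0.41 for the RNA editing enzyme gene APOBEC1 to 3.08 ± 0.39 for the sodium pump gene ATP1B2. The 10 largest falls were in RAB6C, NNAT, GOLGA6A, ZNF107, ZDHHC17, KCNMB3, RCCD1, OLFM4, ARL15 and ZNF490, from -4.52 ± 1.27 for the vesicle traffic gene RAB6C to -3.94 ± 0.72 for the zinc finger gene ZNF490.

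As lists at 180 s and 6 h, immediate early genes had a median of 0.81 log2 with 25 of 26 positive (8 higher, and 8 adjusted over the list alone, camera 0.0058), and interferon-stimulated genes -0.85 with 3 of 23 positive (2 higher and 10 lower, the same numbers adjusted over the list alone, camera 0.012). Neither call held: adjusted p = 0.93 with an estimated correlation for both. ATF4 and unfolded protein response genes had a median of 0.60 with 8 of 23 higher and 0 lower, both over all transcripts and adjusted over the list alone (camera 0.13). NRF2 targets had a median of 0.13 with 4 higher and 2 lower, also when adjusted over the list alone, and NRF2 pathway regulators 0.57 with 3 higher, among them the small MAF gene MAFK (1.71 ± 0.45), and 1 lower, the ubiquitin ligase gene CUL3 (-1.57 ± 0.38). Adjusted over the list alone, p53 targets had 3 genes higher and 8 lower (median -0.29), NF-kB targets 2 and 2 (median 0.59), growth factors 5 and 3 (median 0.19), and G2/M genes 0 and 1 (median -0.34, 8 of 23 positive). Medians lay between -0.10 and 0.18 for other antioxidant enzymes (0.18), heat shock proteins (0.13), G1/S genes (-0.10), keratinocyte differentiation (0.18), basal keratinocyte genes (0.08), metallothioneins (0.14), cholesterol synthesis (0.15), glycolysis and HIF1 targets (0.07), proteasome (0.06), ribosomal proteins (0.17), the mitochondrial chain (0.04), apoptosis regulators (-0.09), reference genes (0.04) and fibroblast markers (0.17). Markers of leukocytes (0.70) and endothelium (0.37) had larger medians. Random lists of matched level had medians of 0.34 and 0.33, which put these 2 lists at percentiles 75.1 and 52.7, so they did not stand out. Of 7 melanocyte markers 4 rose, TYR and SOX10 by 1.97 each, and 2 fell, MITF the most (-3.39). Of the 26 lists, immediate early and interferon-stimulated genes alone passed camera with the preset correlation and 0 passed with the estimated one.

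At 24 h after 180 s, limma called 1 transcript, a count that ran from 0 to 2 when 1 sample or array was left out. PPP1R3C, a gene for a glycogen-targeting subunit of a phosphatase, fell by 3.19 ± 0.30 log2 (SE, 1 sample against 5, limma adjusted p = 0.0205), against 4671 transcripts at an unadjusted p under 0.05. HMOX1 stood at 0.51 (limma adjusted p = 0.595), FOS at -0.76 and IL6 at -2.29 ± 0.62 (limma adjusted p = 0.101). No list passed camera, and ATF4 genes had a median of 0.27. After quantile normalization limma called 1265 transcripts, 648 higher and 617 lower, and PPP1R3C stood at -3.26.

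Many transcripts also differed from untreated at 6 h after the shorter treatments, but HMOX1 passed in neither on the deposited scale. After 20 s and 3 h, MRPS22, a mitochondrial ribosome gene, fell by 5.11 ± 0.32 log2 (limma adjusted p = 0.000106). The tRNA modification gene GON7 (-5.06 ± 0.28), the ephrin gene EFNB2 (-4.85 ± 0.25), YIPF6 (-4.40 ± 0.34) and GLYR1 (-4.39 ± 0.29) fell almost as far. The cornified envelope gene LCE1C (2.69 ± 0.32), SPINK14, GDF7, OR2Z1 and OR52J3 rose most, and HMOX1 stood at 1.31 (limma adjusted p = 0.125). After 60 s and 3 h, MRPS22 fell again, by 5.02 ± 0.32 (limma adjusted p = 0.000509), with the proteasome gene PSMD6 (-3.13 ± 0.30), TUFM (-3.11 ± 0.23), ATP2A2 and the keratin gene KRT15. SCRT1 rose by 2.67 ± 0.33, followed by SPMIP2, OR8J1, SPI1 and CFAP161, and HMOX1 stood at 1.08. At 6 h, GDF1 (3.04 ± 0.68) led the rises after 20 s, with EPCIP, MYF5, FCRL1 and AGXT, and PGLYRP4 (-4.44 ± 0.57) the falls, with ZNF490, GOLGA6A, BMP3 and KRTAP13-1. After 60 s at 6 h they were APOBEC1 (2.99 ± 0.41), CALCA, SPI1, OR52J3 and OPRPN, and RAB6C (-4.97 ± 1.27), ANP32D, GOLGA6A, ARL15 and PSG3. HMOX1 at 6 h was 1.31 after 20 s (limma adjusted p = 0.0788, and 1.58 with 0.0319 after quantile normalization) and 0.19 after 60 s (limma adjusted p = 0.825).

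limma called 1099 transcripts at 20 s and 3 h (625 higher, 474 lower), 3755 at 20 s and 6 h (1994 and 1761), 20 at 60 s and 3 h (7 and 13) and 3647 at 60 s and 6 h (2027 and 1620). Median centring moved the split at 20 s and 6 h to 2518 higher and 1416 lower. It moved the split at 60 s and 3 h to 22 higher and 19 lower, and quantile normalization moved it to 63 and 65. A lone untreated array set against the other 4 gave 23 calls for untreated replicate 4 and 0 for each of the others (2625, 594, 196 and 259 at an unadjusted p under 0.05), so on that scale the 20 calls at 60 s and 3 h are no more than an untreated array alone can give. After quantile normalization the lone untreated arrays gave 0, 0, 0, 38 and 1 calls, against 128 at 60 s and 3 h. Leaving out untreated 2, 3 or 5 gave 210, 149 and 112 at 20 s and 3 h and 6 each at 60 s and 3 h, where leaving out untreated 4 gave 11 and its own array 1 gave 38. At 6 h, leaving out untreated 2 or 5 gave 2349 and 2061 after 20 s, and leaving out untreated 5 gave 2279 after 60 s. At 24 h limma called 0 after 20 s and 0 after 60 s, against 3264 and 1850 at an unadjusted p under 0.05. Interferon-stimulated genes at 20 s and 6 h had a median of -0.65, with 1 higher and 4 lower, or 2 and 8 adjusted over the list alone. At 60 s and 24 h, FOS stood at -0.72, and immediate early genes had a median of -0.53 with 4 of 26 positive and 2 lower when adjusted over the list alone (camera 0.00011, adjusted p = 0.69 with an estimated correlation).

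**Figure D2:**
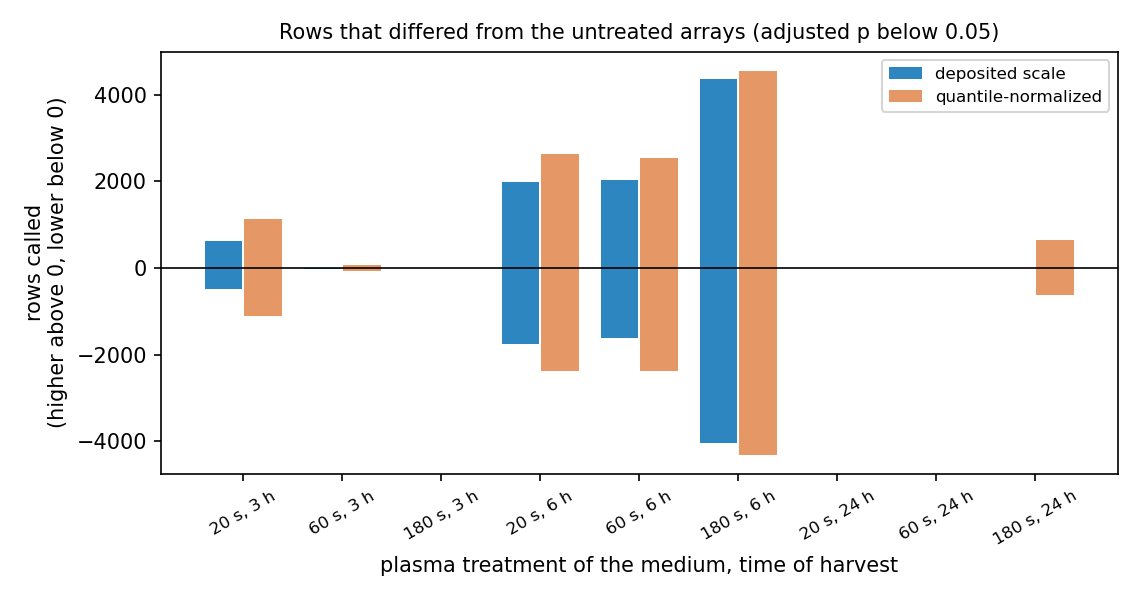
Transcripts called by limma (adjusted p below 0.05) in each of the 9 plasma conditions against untreated, as counts of higher and lower transcripts. Bars are drawn for the deposited scale and after quantile normalization. On the deposited scale the counts reach 8394 at 6 h after 180 s of plasma, and at 24 h no plasma duration passes 1. After quantile normalization the count at 24 h after 180 s is 1265.

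Taking the 3 durations at 1 time as 3 samples, a comparison chosen after the near identity was seen, gave a test with a spread between plasma samples. HMOX1 rose at 3 h by 1.51 ± 0.42 log2, or 2.85-fold (SE, 3 against 5, limma adjusted p = 0.0277), and at 6 h by 1.25 ± 0.42, or 2.37-fold (limma adjusted p = 0.0231), and stood at -0.09 at 24 h (limma adjusted p = 0.915). NQO1 rose by 0.61 ± 0.19 at 3 h and 0.48 at 6 h, and the ferritin light chain gene FTL by 0.90 ± 0.23 and 0.70. CHAC1 rose by 1.94 ± 0.55 at 3 h and by 2.12 at 6 h, and CEBPB, a transcription factor gene of the stress response, by 1.25 ± 0.20 and 1.45. JUND (1.80 ± 0.42) and JUNB (1.59 ± 0.48) rose at 3 h, where FOS stood at 0.92 (limma adjusted p = 0.172), and HBEGF (1.19 ± 0.26, limma adjusted p = 0.00211) and VEGFA (0.88 ± 0.28, limma adjusted p = 0.0166) rose at 6 h. At 24 h JUN, the gene for a FOS partner, fell by 1.97 ± 0.39 (limma adjusted p = 0.035), and ID1, an inhibitor of differentiation, and SREBF1, a lipid synthesis regulator, rose by 1.86 ± 0.36 and 1.59 ± 0.28.

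The antiviral genes split at 6 h in that comparison. OAS2 (-1.82), IFIT1 (-0.98), RSAD2 and HERC5 were among 13 interferon-stimulated genes that fell, while ISG15 (1.00), ISG20 (1.32) and IRF7 (1.21) rose, or 3 higher and 15 lower adjusted over the list alone. The list had a median of -0.65 (camera 0.088, adjusted p = 0.97 with an estimated correlation). Of 24 glycolysis and HIF1 targets 3 rose and 7 fell, both over all transcripts and adjusted over the list alone, PDK1 (-2.02) and BNIP3 (-2.10) among the latter, with a list median of -0.01 (camera 0.66). NRF2 targets had 4 genes higher and 1 lower at 3 h, both over all transcripts and adjusted over the list alone, with a median of 0.08. At 6 h NRF2 targets had 6 higher and 2 lower (5 and 2 adjusted over the list alone), with a median of 0.04 (camera 0.91). Immediate early genes had 6 higher and 0 lower at 3 h (7 and 0 adjusted over the list alone, median 0.61, camera 0.00025, adjusted p = 0.96 with an estimated correlation).

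Over all transcripts, limma called 3730 at 3 h (2146 higher, 1584 lower), 11264 at 6 h (5910 and 5354) and 251 at 24 h (95 and 156), each for 3 plasma samples against 5 untreated. The largest rises were SCRT1 (2.28 ± 0.31), OR52J3, CCDC85B, IL23R and SPINK14 at 3 h, MYF5 (2.77 ± 0.35), APOBEC1, GDF1, OR52J3 and CALCA at 6 h, and ID1, SREBF1, BRAT1, H1-10 and NAPRT at 24 h. The largest falls were MRPS22 (-3.59 ± 0.72), ZNF676, KRTAP13-1, RAB6C and ZNF681 at 3 h, RAB6C (-4.15 ± 0.40), GOLGA6A, ZNF490, ARL15 and PGLYRP4 at 6 h, and KRTAP13-1 (-2.67 ± 0.27), NRXN3, GLYATL2, COXFA4 and PPP1R3C at 24 h. The counts at 3 and 24 h depended on single samples. At 3 h it was 531, 1862 and 2090 without 20, 60 and 180 s, and 2063 and 1654 without untreated 2 and 5. At 24 h it was 3, 2670 and 3 without 20, 60 and 180 s, and 1155, 16, 6, 113 and 14 without untreated 1 to 5.

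**Figure D3:**
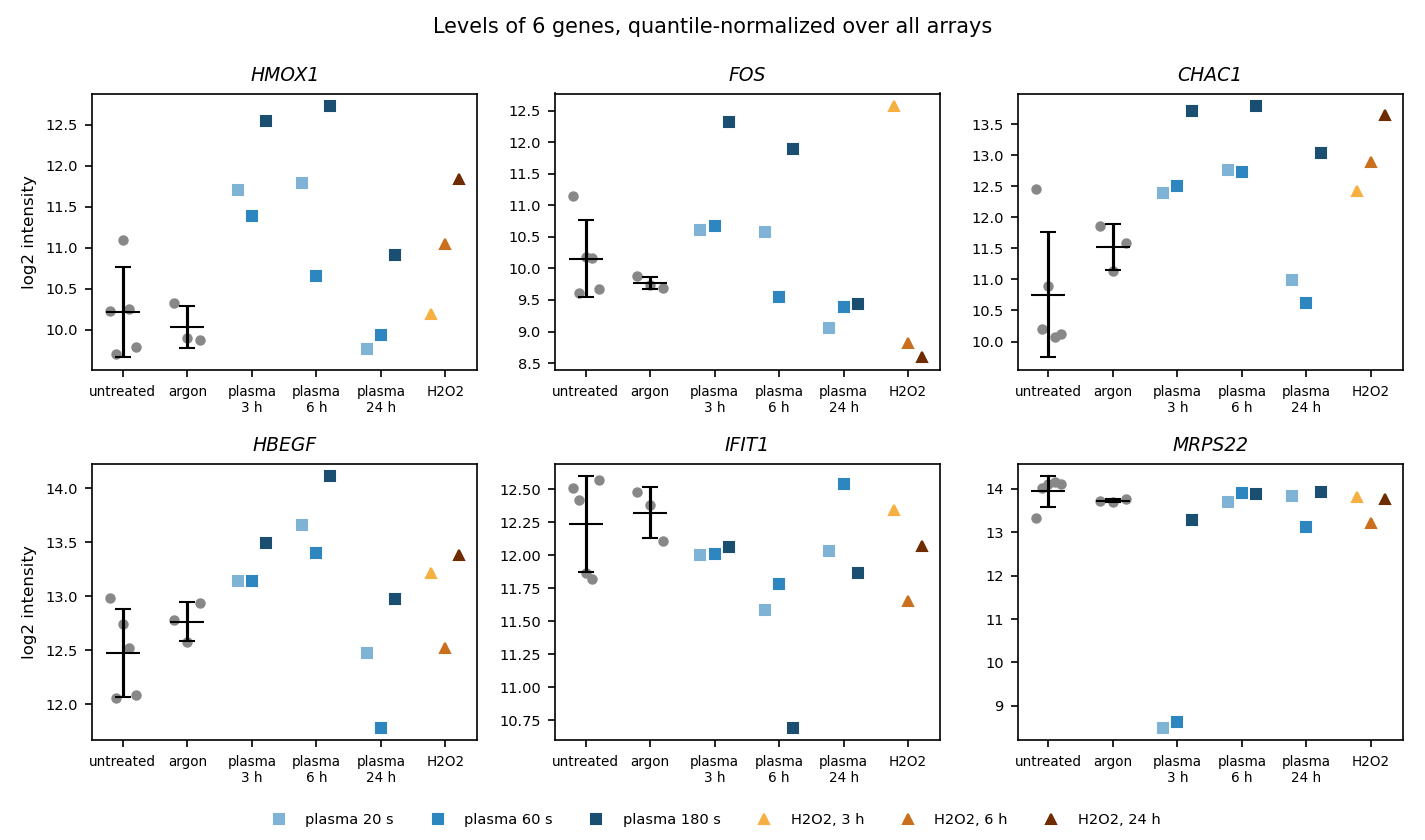
Levels of HMOX1, FOS, CHAC1, HBEGF, IFIT1 and MRPS22 (log2 intensity, quantile-normalized) in each sample, with bars for the mean and SD of the 5 untreated and 3 argon samples. HMOX1 reaches 12.54 and 12.72 at 180 s after 3 and 6 h, against a mean of 10.21 in untreated samples.

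Whether 180 s did more than 20 s was tested at each time. At 3 h the 13 called transcripts were all higher after 180 s, led by 5 genes that had fallen after 20 s: EFNB2 (5.13 ± 0.32 log2, limma adjusted p = 0.000421), GON7 (5.11 ± 0.37), MRPS22 (4.48 ± 0.41), YIPF6 (4.43 ± 0.44) and RPL36A (4.31 ± 0.38). FOS was 1.68 ± 0.60 higher after 180 s and HMOX1 0.84 ± 0.59, neither past the threshold (limma adjusted p = 1). At 6 and 24 h limma called 0 transcripts, against 3240 and 319 at an unadjusted p under 0.05. After quantile normalization it called 1010 at 6 h (419 higher, 591 lower), among them P2RY10 (3.30), KPRP (3.19), GRAMD2B (-4.12) and SLC4A11 (-3.73). At 3 h immediate early genes had a median of 0.43 with 24 of 26 positive (camera 3.4e-05, adjusted p = 0.53 with an estimated correlation). ATF4 genes had a median of 0.34 with 20 of 23 positive (camera 0.0019, adjusted p = 0.36 with an estimated correlation). With time as a block, over 3 samples of each duration, HMOX1 was 0.94 ± 0.30 higher after 180 s and FOS 1.08 ± 0.38 (limma adjusted p = 1 for HMOX1). In that fit 0 transcripts were called against 605 at an unadjusted p under 0.05. There 4 of 26 lists passed camera with the preset correlation and 0 with the estimated one. Among them, immediate early genes had a median of 0.32 (camera 3.1e-07, adjusted p = 0.35 with an estimated correlation). NRF2 targets, also among them, had a median of 0.15 with 24 of 32 positive (camera 0.029, adjusted p = 0.56 with an estimated correlation).

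The values at 24 h were set against those at 3 h within each duration and over all durations. After 180 s, FOS differed by -2.74 ± 0.60 log2 at 24 h (limma adjusted p = 0.831) and IL6 by -3.49 ± 0.80 (limma adjusted p = 0.85). With duration as a block, over 3 samples at each time, JUN differed by -1.91 ± 0.28, FOS by -1.79 ± 0.38, EGR1, another immediate early gene, by -1.65 ± 0.30, HMOX1 by -1.60 ± 0.30 and EREG by -1.25 ± 0.20 (limma adjusted p = 0.2 for JUN, 0.268 for FOS and 0.228 for HMOX1). In that fit limma called 0 transcripts, against 2025 at an unadjusted p under 0.05, and for 6 h against 3 h 0 against 5225. When 1 sample was left out, the calls ran from 0 to 5 for 24 h and from 0 to 1067 for 6 h. Immediate early genes had a median of -0.87 with 1 of 26 positive and 18 lower adjusted over the list alone (camera 2.4e-20, adjusted p = 0.12 with an estimated correlation), and growth factors -0.58 with 11 lower adjusted over the list alone (camera 3e-09, adjusted p = 0.18 with an estimated correlation). Within durations, limma called 13 transcripts after 20 s, 4 after 60 s and 0 after 180 s, against 575, 3008 and 1240 at an unadjusted p under 0.05. They included GON7 (5.74 ± 0.37), MRPS22 (5.01), EFNB2 (4.80), RPL36A (4.72) and YIPF6 (4.61) after 20 s, and MRPS22 (4.24 ± 0.41), KRT15 (3.36), TUFM (3.19) and the keratin gene KRT23 (-2.80 ± 0.32) after 60 s.

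Argon gas alone tested the carrier. KRTAP13-1, a hair keratin-associated gene, fell by 3.25 log2 in 3 argon samples against 5 untreated (limma adjusted p = 0.00872 after quantile normalization), and KRT75, HECW2, COXFA4 and KRT74 fell too. ATP5F1D (2.06), H1-10 (1.89), HSPBP1 (1.68), ID1 (1.66) and S100A6 (1.44) rose. These 10 had the largest changes on the deposited scale. CEBPB (1.01 ± 0.19, limma adjusted p = 0.015), the endoplasmic reticulum chaperone gene SDF2L1 (1.61 ± 0.20) and ISG15 (1.63 ± 0.44) rose too, while HMOX1 stood at -0.18 ± 0.30 (limma adjusted p = 0.718). On the deposited scale HMOX1 stood at -1.32 with a limma adjusted p of 0.00329, where the median of all transcripts was -1.01. limma called 15952 transcripts on the deposited scale (1145 higher, 14807 lower), 2825 after quantile normalization (1554 and 1271) and 8968 higher and 4962 lower after median centring.

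Against argon, HMOX1 was higher in the mean of all plasma groups by 1.23 ± 0.27 log2 (SE, 9 samples against 3, limma adjusted p = 0.0342 after quantile normalization). SPINK14 (2.24), DEFB121 (1.77), CRYGA (1.74), RAMP3 (1.67) and CALCA (1.65) rose, and CSNK1A1L (-2.66), MRPS22, PSMD6 (-1.16), TUFM (-0.75) and RPL36A (-0.72) fell, the 10 having the largest changes on the deposited scale. Of these, 4 means rest on 1 or 2 of the 9 plasma samples: against untreated, RPL36A stood at -4.54 after 20 s at 3 h and between -0.39 and 0.30 in the other 8. MRPS22 (-5.45 and -5.32), PSMD6 (-4.49 and -3.34) and TUFM (-3.95 and -3.32) were low after 20 and 60 s at 3 h, and between -0.82 and 0.18 in the other 7. limma called 14422 transcripts on the deposited scale (13845 higher, 577 lower), where the median of all transcripts was 0.93, 1157 after quantile normalization (667 and 490), and 7249 higher and 9744 lower after median centring. Split by time, HMOX1 was 1.84 ± 0.48 higher at 3 h (limma adjusted p = 0.205), rose by 1.69 ± 0.48 at 6 h (limma adjusted p = 0.0494) and stood at 0.17 at 24 h, each over 3 plasma samples. limma called 6 transcripts at 3 h (0 higher, 6 lower), 2229 at 6 h (1189 and 1040) and 0 at 24 h, against 1740 at an unadjusted p under 0.05 at 24 h. On the deposited scale the splits were 12749 and 383 at 3 h and 11538 and 365 at 6 h. These counts depended on single samples: at 6 h it was 3507 without 20 s, 45 without 180 s, and 535, 5 and 1339 without argon 1 to 3. At 3 h it was 0, 0 and 10 without 20, 60 and 180 s, and 2, 3 and 0 without argon 1 to 3, and at 24 h 1 without argon 1. APOL4 (-2.04 ± 0.27) and AFM (-1.66) fell at 3 h, and CALCA (2.87 ± 0.49) rose and RAB6C (-3.31) fell at 6 h. At 3 h 5 of 26 lists passed camera with the preset correlation: immediate early genes (median 0.39, 25 of 26 positive, camera 2.6e-06), ATF4 genes (0.30, camera 0.0199), growth factors (0.18, camera 0.0266), G2/M genes (-0.21, 1 of 23 positive, camera 0.0199) and cholesterol synthesis (-0.22, camera 0.0266), each with an adjusted p = 0.58 with an estimated correlation and 0 genes past the threshold when adjusted over the list alone. At 6 h 0 lists passed. At 24 h immediate early genes (median -0.41, 2 of 26 positive, 5 lower adjusted over the list alone, camera 4.7e-06), growth factors (-0.34, 2 lower adjusted over the list alone, camera 0.00019) and NF-kB targets (-0.25, camera 0.0096) passed, with an adjusted p = 0.57, 0.51 and 0.57 with an estimated correlation.

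H2O2 served as the oxidant control. CHAC1 rose by 2.23 ± 0.48 log2 over 3 H2O2 samples against 5 untreated (limma adjusted p = 0.0208 after quantile normalization), while HMOX1 stood at 0.81 ± 0.36 (limma adjusted p = 0.166), with 1 array each at 10.19, 11.04 and 11.83 log2 intensity after 3, 6 and 24 h. FOS stood at -0.16, with 12.57 at 3 h against 8.83 and 8.59 later. MAP1B (2.63), PROKR2 (2.26), CYP1A2 (2.17) and TCF20 (1.60) rose, and MAK16 (-4.62), a ribosome assembly gene, PGCKA1, TOX, GLYATL2 and DBF4 fell. The interferon-stimulated genes IFI44, RSAD2 and HERC5 (-2.12 each) were among 6 of 23 that fell (7 adjusted over the list alone). Their list median was -0.45 (camera 0.00031, adjusted p = 0.4 with an estimated correlation), and G2/M genes had a median of -0.63 with 2 of 23 positive (camera 0.00031, adjusted p = 0.59 with an estimated correlation). ATF4 genes had a median of 0.27 with 19 of 23 positive (camera 0.009, adjusted p = 0.4 with an estimated correlation). limma called 13004 transcripts on the deposited scale (1210 higher, 11794 lower), where the median of all transcripts was -0.71, 1948 after quantile normalization (1014 and 934), and 7501 higher and 4268 lower after median centring.

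Set against H2O2 at matched times, 180 s of plasma gave HMOX1 1.04 ± 0.63 log2 higher and IL6 1.75 higher, neither past the threshold (limma adjusted p = 0.337 and 0.15 after quantile normalization). On the deposited scale IL6 passed (2.66, limma adjusted p = 0.0121). After quantile normalization 9 of 26 lists passed camera with the preset correlation, and 0 passed with the estimated one. In simulated data for this comparison, camera with the estimated correlation did not call a list shifted by 1 log2. Its lack of calls here therefore does not speak against the lists. Ribosomal protein genes had a median of 0.33 with 28 of 32 positive (camera 0.016, adjusted p = 0.75 with an estimated correlation). NRF2 targets (0.29), other antioxidant enzymes (0.31), heat shock proteins (0.33), immediate early genes (0.42), G2/M genes (0.29), cholesterol synthesis (0.40) and proteasome genes (0.30) shared a camera adjusted p of 0.0454, and metallothioneins (0.50) had 0.0497, against 0.70 or 0.89 for each with an estimated correlation. On the deposited scale camera put NRF2 targets in the other direction (adjusted p = 0.28), though their median was 0.25. There 3 lists passed with the preset correlation, all as lower relative to the other transcripts, where the median of all transcripts was 0.68. They were basal keratinocyte genes (median -0.39, camera 0.0029), proteasome genes (median -0.01, camera 0.016) and the mitochondrial chain (median -0.03, camera 0.030). Each had an adjusted p = 0.67 with an estimated correlation. Proteasome genes thus passed in opposite directions on the 2 scales, on the deposited one only relative to the 0.68 of all transcripts. limma called 0 transcripts after quantile normalization, against 6164 at an unadjusted p under 0.05. On the deposited scale it called 11119 (10222 higher, 897 lower, or 5258 and 5710 after median centring), where the median of all transcripts was 0.68 and MAK16 (5.61) and SPDYA (4.68) were highest and NNAT (-3.30) was lowest.

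Changes against untreated were compared across durations, at 6 h also as calls. Of transcripts called after both 60 and 180 s, 1815 were higher in both, where independent lists would share 367, and 1401 were lower in both, against 273, with 0 opposite. After 20 and 180 s, 1667 were higher in both and 1444 lower in both, against 361 and 297, with 6 opposite. The correlation of changes across genes, which are not independent, was 0.858 for 60 and 180 s at 6 h and 0.799 for 20 and 180 s, against a simulated 0.165 to 0.168 for unchanged groups that share the untreated arrays. The covariance for 20 and 180 s was 0.883, against a simulated 0.0281. At 3 h the correlation was 0.810 for 20 and 180 s (0.634 and 0.745 with separate untreated arrays) and 0.746 for 60 and 180 s (0.555 and 0.654). At 24 h it was 0.794 for 20 and 180 s (0.672 and 0.644) and 0.238 for 60 and 180 s (0.195 and 0.0494). Over all comparisons, 19 list calls held with an estimated correlation. They lay in argon against untreated (10), plasma against argon (7) and H2O2 against untreated (2) on the deposited scale, with arrays whose distribution of intensities differed, and 0 held after quantile normalization.

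**Figure D4:**
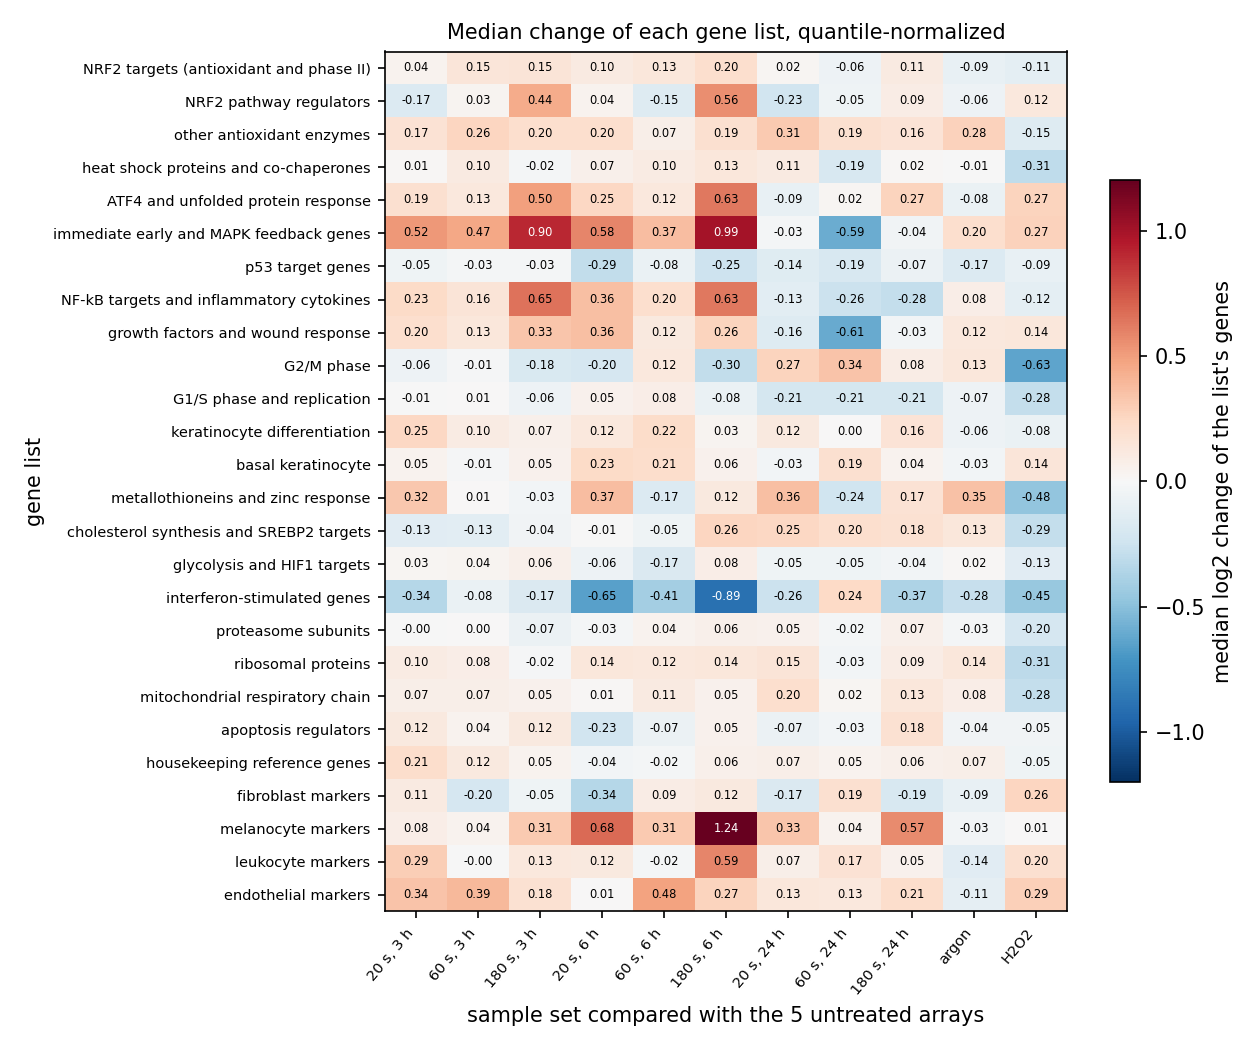
Median log2 change of each gene list against untreated (quantile-normalized) in the 9 plasma conditions, argon and H2O2, shown as colour. Immediate early genes stand above 0 after each duration at 3 and 6 h, and also in argon (0.20) and H2O2 (0.27). Interferon-stimulated genes stand below 0 in every column except 60 s at 24 h (0.24), with argon at -0.28 and H2O2 at -0.45.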

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

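The housekeeping and interaction results below came from rules fixed before the data were examined, while the tests of the 3 patterns (the likeness of the plasma arrays, the many changes at 6 h, and the argon samples) and the counts of other splits for the added comparisons were chosen after the results were seen.

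Among 39 measures over the 5 untreated samples, 1 sample stood apart in 1 measure. The reference genes, such as ACTB for actin and RPLP0 for a ribosomal protein, which many studies take as constant, had a median deviation of -0.0593 log2 in untreated replicate 5, against -0.0024 to 0.0141 in the other 4. Chance sets 1 sample apart in about 1 in 20 such groups, and no explanation was tested.

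The change from 20 to 180 s differed between 24 and 3 h for 5 transcripts, 4 of which have a symbol. The count was 11 after quantile normalization, lower after median centring, and ran from 5 to 11 when 1 sample or array was left out. GON7, a gene for part of a tRNA-modifying complex, had a difference of -5.63 ± 0.52 log2 (limma adjusted p = 0.00881), EFNB2 -5.45 ± 0.45 (0.00648), the ribosomal gene RPL36A -4.80 ± 0.53 (0.032) and PITPNB, a lipid transfer gene, -3.94 ± 0.47 (0.0371). After 20 s at 3 h their changes against untreated, after quantile normalization, were -5.26, -5.19, -4.54 and -4.24, and after 180 s at 3 h 0.10, 0.27, -0.04 and -0.06, so each difference rests on the lone 20 s sample. Interferon-stimulated genes had a median difference of -0.42 with 4 of 23 positive (camera 0.0039, adjusted p = 0.79 with an estimated correlation).

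The first pattern is the likeness of the 3 arrays of a plasma group, over all genes measured. The largest median SD of a plasma group was 0.1001 log2, below the 0.207 to 0.301 of the 10 sets of 3 untreated arrays, which argues against separate cultures that vary as the untreated arrays do. In 6 of 9 groups most transcripts of the median pair lay within 0.01 log2 of the pair's offset, which is consistent with 1 measurement entering several deposited columns. At 60 s and 24 h that share was 4.15%, near the 3.04% of the closest untreated pair, so the likeness was not equal in all groups. No biological explanation was tested.

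The second pattern is the number of changes at 6 h, where HMOX1, HBEGF and CHAC1 rose together with OR52J3, MYF5 and CALCA, which encode an odorant receptor, a muscle transcription factor and a neuropeptide. After quantile normalization limma still called 10196 transcripts at 6 h, which argues against a difference in scale between arrays. The 364 olfactory receptor genes, which keratinocytes are not known to make in quantity, had a median change of 0.8031 log2 at 180 s and 6 h, against 0.45 for 2000 matched lists (percentile 100). Signal that does not come from those transcripts predicted a rise like that of matched genes, which the larger value did not meet, and no value in the tables excludes it, so it was left open. A batch of arrays shared by the 6 h samples cannot be told apart from time, because each 6 h sample would belong to it. With duration as a block, 5225 transcripts had an unadjusted p under 0.05 for 6 h against 3 h. In that fit limma called 0, and from 0 to 1067 when 1 sample was left out. A response of the cells at 6 h stays open, and was not separately tested.

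The third pattern is that argon samples differed from untreated ones much as plasma samples did, with ID1, H1-10 and CEBPB higher and KRTAP13-1 and COXFA4 lower in both. Across transcripts, which are not independent, changes in argon and in plasma at 24 h correlated at 0.741. With separate untreated arrays for each the lower value was 0.5196, so the shared untreated arrays alone do not account for it. A separate normalization that argon shared with the H2O2 arrays is argued against as the whole cause. The intensities of the H2O2 arrays also differed from the untreated ones, yet their correlation with argon was lower than that of plasma at 24 h by at least 0.3553. Lower quartiles ran from 99 to 107 in H2O2 arrays and from 78 to 81 in argon arrays, and H2O2 is a treatment of its own. A shift peculiar to the argon arrays was therefore not tested. Handling or time of harvest shared by argon and plasma samples cannot be told apart from an effect of the gas, since the labels give argon no time. Between plasma at 24 h and argon limma called 0 transcripts, and 1740 had an unadjusted p under 0.05, a level that unchanged transcripts also reach.

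Other splits of the same samples were used to ask whether chance alone gives as many calls as the real groups do. For plasma at 3 h, where HMOX1 and CHAC1 rose, 1 of 56 splits (the real one) called as many as the real 3730, and the highest other called 147. For plasma at 6 h it was 1 of 56, with 11264 against 1, and for plasma at 24 h, where JUN fell, 2 of 56, with 251 against 305. At 3 and 6 h this argues against a random relabelling of the samples as the source of the counts. The splits cannot address a difference that all plasma samples share, such as time or batch. At 3 h the count also ran from 531 to 4262 when 1 sample was left out. At 24 h the share was under 0.05 too, but 1 other split called more than the real groups and the count rests on single samples (3 to 2670 when 1 is left out), so chance is not taken as excluded there. For argon it was 1 of 56, with 15952 against 0 on the deposited scale and 2825 against 0 after quantile normalization. For H2O2, where CHAC1 rose, it was 1 of 56, with 13004 against 0 on the deposited scale and 1948 against 1209 after quantile normalization. For plasma against argon, 1 of 100 splits called as many as the real 14422 on the deposited scale (highest other 9375). After quantile normalization 6 of 100 called as many as the real 1157, so chance was not excluded for it, and the highest other, 4152, points to a structure of the samples beyond the groups.

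In the remaining comparisons there are 10 splits, too few for a share under 0.05. For 180 s of plasma against H2O2 the real value was 11119 and the highest other 0. For plasma against argon after quantile normalization these were 6 and 0 at 3 h, 2229 and 0 at 6 h, and 0 and 4 at 24 h. For 180 s against 20 s over the 3 times, 6 h against 3 h and 24 h against 3 h over the 3 durations, the real value and the highest other were 0 by limma, and all 10 splits called as many. The counts at an unadjusted p under 0.05 were 1740 for the comparison with argon at 24 h and 605, 5225 and 2025 for the last 3.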

How the results depend on the processing

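The arrays as deposited, argon as control after quantile normalization, the deposited scale for the added comparisons with argon, and quantile normalization of the gene list tests were chosen after the results were seen. The cause was not tested for the moves below except where the construction gives it. HMOX1 at 180 s and 6 h passed under every alternative run for it, from 2.11 to 3.56 log2. Named genes reversed direction 11 times under median centring, 3 on the deposited scale and 1 with argon as control, each given below. Detection calls were not used here, so signal near the array background limits what low transcripts can show.

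With the arrays as deposited, 3 closely similar arrays per plasma group entered as replicates, which by construction shrinks the spread. For 20 s, limma then called 15778, 17337 and 13324 transcripts at 3, 6 and 24 h, for 60 s 13262, 16512 and 10598, and for 180 s 13547, 18238 and 14551. For 180 s against 20 s it called 7663, 13577 and 7377 at these times, for 24 against 3 h 8507, 14768 and 10569 after 20, 60 and 180 s, for the interaction 8155 and for 180 s against H2O2 18333. With a replicate block on those arrays the counts were 17319, 18653 and 15671 for 20 s, 15626, 17842 and 13865 for 60 s, and 15834, 19396 and 16605 for 180 s. They were 12393, 16792 and 12334 for 180 s against 20 s, 13225, 17793 and 14444 for 24 against 3 h, and 12945 for the interaction. The numbers did not pair the arrays: same-numbered arrays had correlations of deviations from -0.103 to 0.065 (135 pairs), and others -0.058 to 0.103 (324 pairs).

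With argon as control on the deposited scale, plasma gave 9745, 10177 and 10236 after 20 s at 3, 6 and 24 h, 11257, 9929 and 11392 after 60 s, and 10877 and 10448 after 180 s at 3 and 24 h, where the other distribution of argon intensities moves the median of all transcripts. KRTAP13-1 at 20 s and 6 h reversed to 1.60. After quantile normalization argon as control gave 86 and 161 after 20 s at 3 and 6 h, 1146 after 60 s at 6 h and 0 after 180 s at 24 h. On the deposited scale, plasma against argon gave 13132, 11903 and 13606 at 3, 6 and 24 h, and at 3 h AFM, TMEM178A and CYP4F2 reversed to 0.22, 0.40 and 0.61.

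Quantile normalization gave 2247 for 20 s at 3 h, 128 for 60 s at 3 h, 1 for 60 s at 24 h, 1265 for 180 s at 24 h, 1010 for 180 s against 20 s at 6 h, 9 for 24 against 3 h after 60 s and 11 for the interaction. It gave 2825 for argon, 1157 for plasma against argon, 1948 for H2O2 and 0 for 180 s against H2O2 by limma, with 6164 at an unadjusted p under 0.05. Calls of gene lists went from 90 to 48 with it and to 19 with an estimated correlation. Median centring gave 41 for 60 s at 3 h, 41 for 180 s against 20 s at 6 h and 3 for the interaction. It reversed GCLM (0.64), DDIT3 (0.33) and VEGFA (0.89) in argon, NQO1 (-0.82), GCLM (-0.63), HSPA1A (-1.04), DDIT3 (-0.13), HBEGF (-0.76) and VEGFA (-0.36) in plasma against argon, and HSPA1A (0.55) and DDIT3 (0.83) in H2O2.

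Fits of the compared groups alone gave 2918 for 20 s at 3 h, 392 for 60 s at 3 h, 5599 for 60 s at 6 h and 1611 for 180 s at 24 h, and they could not be fitted for the comparisons of durations, times and the interaction, with 1 sample on each side. Array weights gave 4054, 7270 and 308 after 20 s at 3, 6 and 24 h, 877, 6571 and 3 after 60 s, and 189 and 2521 after 180 s at 3 and 24 h. They gave 986 for 180 s against 20 s at 6 h, 26 for 24 against 3 h after 60 s and 14 for the interaction. Trend and robust settings gave 441 for 20 s at 3 h, 1 for 60 s at 24 h, 1 for 180 s at 3 h, 1 for 180 s against 20 s at 6 h, 11 for 24 against 3 h after 60 s and 12 for the interaction. Without the 25% of transcripts with the lowest mean, the counts were 38 for 60 s at 3 h, 1 for 60 s at 24 h, 0 for 180 s at 24 h, 116 for 180 s against 20 s at 6 h and 11 for the interaction. They were 9955 for argon, 8386 for plasma against argon, 7242 for H2O2, 5157 for 180 s against H2O2 and 0 for plasma at 3 h against argon, with fewer transcripts tested. Averaging transcripts per gene gave 1 for 60 s at 24 h, 7 for 180 s at 24 h, 58 for 180 s against 20 s at 6 h and 10 for the interaction.

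Leaving out 1 sample or array at a time gave 112 to 1170 for 20 s at 3 h, with 210, 149 and 112 without untreated 2, 3 and 5, and 2061 to 4188 for 20 s at 6 h, with 2349 and 2061 without untreated 2 and 5. It gave 6 to 38 for 60 s at 3 h, with 6 without untreated 2, 3 or 5, 11 without untreated 4 and 38 without its own array 1, and 2279 to 3664 for 60 s at 6 h, with 2279 without untreated 5. For 180 s it gave 7230 to 8694 at 6 h and 0 to 2 at 24 h, with 2 without untreated 1 and 0 without each other untreated array. For 20 and 60 s at 24 h and 180 s at 3 h it gave 0 to 0. For 180 s against 20 s it gave 13 to 13 at 3 h, 0 to 24 at 6 h, with 24 and 20 without arrays 1 and 3 of 20 s, and 0 to 0 at 24 h and over all times. For 24 against 3 h it gave 13 to 13, 4 to 5 and 0 to 0 after 20, 60 and 180 s, and for the interaction 5 to 11, with 11 without array 1 of 180 s at 24 h. For argon it gave 14633 to 16243, for plasma against argon 13150 to 14439, for H2O2 11077 to 13180, for 180 s against H2O2 8684 to 11145 and for calls of gene lists 87 to 93.

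In the added comparisons it gave 531 to 4262 for plasma at 3 h, with 531, 1862 and 2090 without 20, 60 and 180 s and 2063 and 1654 without untreated 2 and 5. At 6 h it gave 8236 to 11540. At 24 h it gave 3 to 2670, with 3, 2670 and 3 without 20, 60 and 180 s and 1155, 16, 6, 113 and 14 without untreated 1 to 5. Against argon it gave 0 to 10 at 3 h, with 0, 0 and 10 without 20, 60 and 180 s and 2, 3 and 0 without argon 1 to 3. At 6 h it gave 5 to 3507, with 3507 without 20 s, 45 without 180 s and 535, 5 and 1339 without argon 1 to 3, and at 24 h 0 to 1, with 1 without argon 1. For 6 against 3 h it gave 0 to 1067, with 1067 without 20 s at 6 h and 4 without 180 s at 3 h, and for 24 against 3 h 0 to 5, with 5 without 180 s at 3 h. A sample left alone on 1 side was assumed to vary like the others.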

Other observations

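The comparison of times over 3 durations and the tests of collapsed and olfactory receptor genes were chosen after the results were seen.

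Between 3 and 24 h, 0 of 26 lists passed camera with an estimated correlation, and the values below passed with the preset one alone. With duration as a block, over 3 samples at each time, the G2/M list, genes made as cells enter mitosis, had a median of 0.27 log2 with 21 of 23 positive (camera 0.00011, adjusted p = 0.36 with an estimated correlation). The G1/S list, genes of DNA replication, had a median of -0.19 with 4 of 22 positive (camera 0.015, adjusted p = 0.18 with an estimated correlation). The cholesterol synthesis list had a median of 0.29 with 18 of 20 positive (camera 0.00011, adjusted p = 0.24 with an estimated correlation). NF-kB targets had a median of -0.43, and 10 were lower and 1 higher when adjusted over the list alone (camera 0.0001, adjusted p = 0.18 with an estimated correlation). ATF4 genes had a median of -0.16 with 4 lower when adjusted over the list alone (camera 0.012, adjusted p = 0.18 with an estimated correlation).

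Some genes were very low in 1 or 2 plasma samples at 3 h. Falls below -3 log2 were not particular to that time, and those called were most numerous at 6 h after 180 s. After 20 s and 3 h, 14 genes had limma calls below -3 log2 after quantile normalization. Of them 11 were the genes for mitochondrial and proteasome parts MRPS22 (-5.45), TUFM (-3.95) and PSMD6 (-4.49), the endosome sorting gene VPS35 (-4.67), GON7 (-5.26), EFNB2 (-5.19), YIPF6 (-4.73), GLYR1 (-4.72), RPL36A (-4.54), PITPNB (-4.24) and MAK16 (-4.04). Of the 14, 6 were also called lower after 60 s at 3 h, with MRPS22 at -5.32 and PSMD6 at -3.34. After 180 s at 3 h, where limma called 0 transcripts in all (3884 at an unadjusted p under 0.05), MRPS22 stood at -0.66 and PSMD6 at -0.47. The remaining 3 of the 14 were low more widely: OLFM4, KRTAP13-1 and ZNF490 stood at -2.52, -2.67 and -1.52 after 180 s at 3 h and at -2.05, -3.25 and -1.89 in argon. At 6 h after 20 s MRPS22 stood at -0.25 and PSMD6 at 0.18. MAK16 stood at -4.62 in H2O2. These genes, VPS35 among them, were grouped after their values were seen.

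Olfactory receptor genes encode odorant receptors. Of 364 such genes 138 were called higher and 7 lower at 180 s and 6 h after quantile normalization. At 3, 6 and 24 h their median change was 0.42, 0.11 and 0.39 log2 after 20 s, 0.35, 0.61 and -0.05 after 60 s, and 0.28, 0.80 and 0.45 after 180 s. In the H2O2 sample at 6 h it was 0.29, within the range of the plasma samples, so a rise was not particular to plasma. Over all transcripts at 180 s and 6 h, split by untreated level into 5 classes of 4800, the median change from the lowest class to the highest was 0.42, 0.86, -0.66, -0.26 and -0.04.

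Among list members in H2O2, after quantile normalization, the HIF1 targets BNIP3 (-2.07) and PDK1 (-1.98) and the growth factor gene FGF2 (-1.98) fell, as did the sterol genes STARD4 (-1.61) and HMGCR (-0.99), while the metallothionein gene MT1E (0.71) rose and MT1X (-1.56) fell. Ribosomal protein genes had a median of -0.31 with 4 of 32 positive (camera 0.00031, adjusted p = 0.4 with an estimated correlation).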
